A study of Mus musculus and Xenopus laevis with 39 samples.

How the data were processed

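CUT&Tag, in which an antibody against a chromatin protein directs a transposase to cut and tag the DNA beside it, was applied to cultured limb explants of mouse and of the frog Xenopus laevis. The series holds 39 samples, 22 from mouse and 17 from Xenopus, each made from 5 pooled limbs in mouse and 8 in Xenopus per the labels' protocols. Peak lists of 26 samples were analysed. The 13 samples of total histone H3 were not analysed here as samples of their own. Groups were taken from the sample titles, which give the species, the culture format (ALI or 96-well), the histone mark and a replicate number. The series design speaks of hypoxic and atmospheric oxygen, and the labels do not say which format stands for which, so the groups are called by format throughout. Nothing in the labels says whether the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

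Per the submitters' processing notes, Bowtie2 2.4.5, deepTools 3.5.6 and MACS3 3.0.1 were used, and hg38 is the only genome build named. The chromosome names in the deposited lists are those of mouse and Xenopus and not of hg38, so the build of these lists is not given in the sources used here, and coordinates are printed as deposited. Peaks had been called by the authors separately for each library, since each deposited list belongs to 1 sample. The peak names of 26 of 26 lists contain the words for an H3 control. The series holds no H3 sample of mouse ALI replicate 2, so the control of the lists of that replicate cannot be matched by replicate number. The deposited columns are a peak score, a fold enrichment ratio over the control, and the −log10 of a p-value and of a q-value, all as the authors' peak caller wrote them. These are the peak's own values and were used only to rank or filter peaks within a list. The lowest −log10 q in a deposited list lay between 1.01 and 1.90. The lists hold no read counts, so the sequencing depth of each library is unknown, and no counting interval is given. A longer list may mean a deeper or cleaner library as well as more marked chromatin.

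Only nuclear chromosomes were used, 21 in mouse and the 9 L and 9 S chromosomes in Xenopus. Peaks on the mitochondrial genome, a spike-in sequence and unplaced contigs were left out, at most 0.241% of the peaks of a list. For each library the number of peaks, the length they cover, their median width, and the share of length in peaks of 5 kb or wider were computed from the deposited intervals. Pairs of libraries were compared by the base-pair Jaccard index (shared length over the length covered by either). The highest index among 74 pairs of libraries was 0.656, so no list repeats another. Bins of 1 kb were called marked where peaks covered at least 50% of them.

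The change of each region was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on the percent of each 5 kb bin covered by peaks, for bins touched by a peak in at least 2 libraries, each species and mark alone, with Benjamini-Hochberg adjustment and a threshold of 0.05. Promoter windows had been planned. The available mouse gene table is of assembly GRCm38.p6, and genes in it extend past the last mouse peak on 11 of 21 chromosomes. Of its protein-coding gene boundaries, 5.19% lay within 500 bp of an H3K4me3 peak of 2 kb or wider in 96-well replicate 1, against 2.63% to 3.21% after the table was shifted along the chromosomes. The table was therefore not used, no Xenopus annotation was used here, and the fixed fallback of 5 kb bins took the place of promoters. Tests of gene lists and of promoters carrying both marks were not run for the same reason, and regions are given by position without gene names. The percent of H3K4me3 length lying under H3K27me3 peaks of the same culture and replicate number was added after the data were seen.

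Library values were compared by exact permutation tests, two-sided, over all regroupings of the libraries, on log2 values for numbers and lengths, and overlap by a one-sided exact permutation of the culture labels. Differences are 96-well minus ALI. The share of bins in which the cultures do not overlap by chance was taken over all regroupings of the libraries, each bin with its ties. In all, 32 tests of library values, overlap and species differences were made, and Benjamini-Hochberg adjustment was applied over them. The bins named were fixed by rule before the data were examined: up to 5 per direction past the threshold, or, where none passed, the 5 with the largest and the 5 with the smallest difference among bins whose cultures do not overlap. Tests were checked on simulated data made from the real bins with 200 bins shifted. A shift of 40 points of covered percent was recovered in 65% of shifted bins for mouse H3K4me3, 49% for Xenopus H3K4me3, and 0% for mouse and Xenopus H3K27me3, and a shift of 20 points in 0% for each of the 4 comparisons. Values were drawn independently with each bin's mean and SD over the libraries of both cultures. They therefore lack differences between whole libraries and do not stand for bins with hardly any spread.

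Replicate numbers pair samples across cultures by label, since libraries with the same species and number share the date-like stamp in their library name. The deviations of same-numbered libraries from their culture means correlated at 0.00 to 0.20 in mouse H3K4me3, −0.06 to 0.38 in mouse H3K27me3, 0.23 to 0.57 in Xenopus H3K4me3 and 0.42 to 0.52 in Xenopus H3K27me3, taken across 5 kb bins. Libraries of different numbers gave −0.19 to 0.13, −0.43 to 0.42, −0.50 to −0.01 and −0.52 to 0.04 in the same order. Deviations from a culture mean cancel within the culture, so these values are not independent of those for the same number. The deviations of the 2 ALI libraries of Xenopus H3K27me3 mirror each other, so their values are not independent. The unpaired fit was fixed as the main one, and the fit with replicate number as a block was an alternative. Other alternatives were a stricter threshold (−log10 q of 5 or more), an equal number of the best peaks per library, each library left out in turn, other bin rules, quantile normalization, no filter beyond 1 library touched, and covered length as a covariate. Bins of 2 kb and 10 kb, the alternatives of the stricter-threshold bins, and leaving out libraries for the share in wide peaks, were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.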

Results

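Peak lists of 2 histone marks were compared between explants kept in 96-well culture and in ALI culture. H3K4me3 is found at active and poised promoters, and H3K27me3 marks chromatin repressed by Polycomb. Mouse lists comprised 4 96-well and 4 ALI libraries for H3K4me3, and 4 and 3 for H3K27me3. Xenopus lists comprised 3 and 3 for H3K4me3, and 3 and 2 for H3K27me3. Peak numbers ranged from 36903 to 81645 for mouse H3K4me3, from 59789 to 231718 for mouse H3K27me3, from 51762 to 139155 for Xenopus H3K4me3 and from 79031 to 336813 for Xenopus H3K27me3. Read depth behind these lists is unknown. None of the 32 tests of library values, overlap and species differences passed adjustment, the lowest adjusted p being 0.8. For library values and overlap, the exact permutation tests allow no p under 0.0286 in mouse and 0.1 in Xenopus. None of those tests could therefore pass adjustment over 32 tests, and this outcome is no evidence against a difference.

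The first comparison asked whether H3K4me3 differs between culture formats in mouse limb explants. Peaks covered 60.3 Mb ± 3.32 (SD, n = 4) in 96-well culture and 56.3 Mb ± 20.0 (SD, n = 4) in ALI culture. The 96-well libraries lay close together, between 56.1 and 63.1 Mb, while ALI replicates 1, 2 and 3 covered 45.7, 55.0 and 39.9 Mb and ALI replicate 4 covered 84.8 Mb. Wide H3K4me3 peaks, of 5 kb or more, numbered 1246 ± 128 (SD, n = 4) in 96-well and 914 ± 744 (SD, n = 4) in ALI. They held 14.3% ± 1.39 (SD, n = 4) of the covered length in 96-well culture against 9.82% ± 4.51 (SD, n = 4) in ALI culture, higher in 96-well in 3 of 4 pairs of the same replicate number. Neither covered length (p = 0.543) nor the wide share (p = 0.143) differed by more than the spread between libraries in the exact permutation test, whose smallest possible p is 0.0286. Without ALI replicate 4 the log2 difference in covered length rose from 0.16 to 0.37. The ALI means then fell to 547 ± 157 (SD, n = 3) wide peaks and a wide share of 7.61% ± 1.04 (SD, n = 3). Each of these 3 measures then had an exact permutation p of 0.0286, not adjusted. ALI replicate 4 was the only ALI library above any 96-well library on them, so leaving it out gives the smallest possible p. Without each other library in turn the exact permutation p ran from 0.543 to 0.943 for covered length and from 0.143 to 0.257 for the wide share. Peak number gave an exact permutation p of 0.743. Lists of the same culture had a mean Jaccard index of 0.580 and lists of different cultures 0.567, with a one-sided exact permutation p of 0.171. The difference of 0.013 rose to 0.035 without ALI replicate 1 and 0.047 without ALI replicate 4, each with an exact permutation p of 0.0286, and it turned to −0.0076, −0.0071, −0.0046 and −0.0093 without 96-well replicates 1, 2, 3 and 4.

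**Figure D1:**
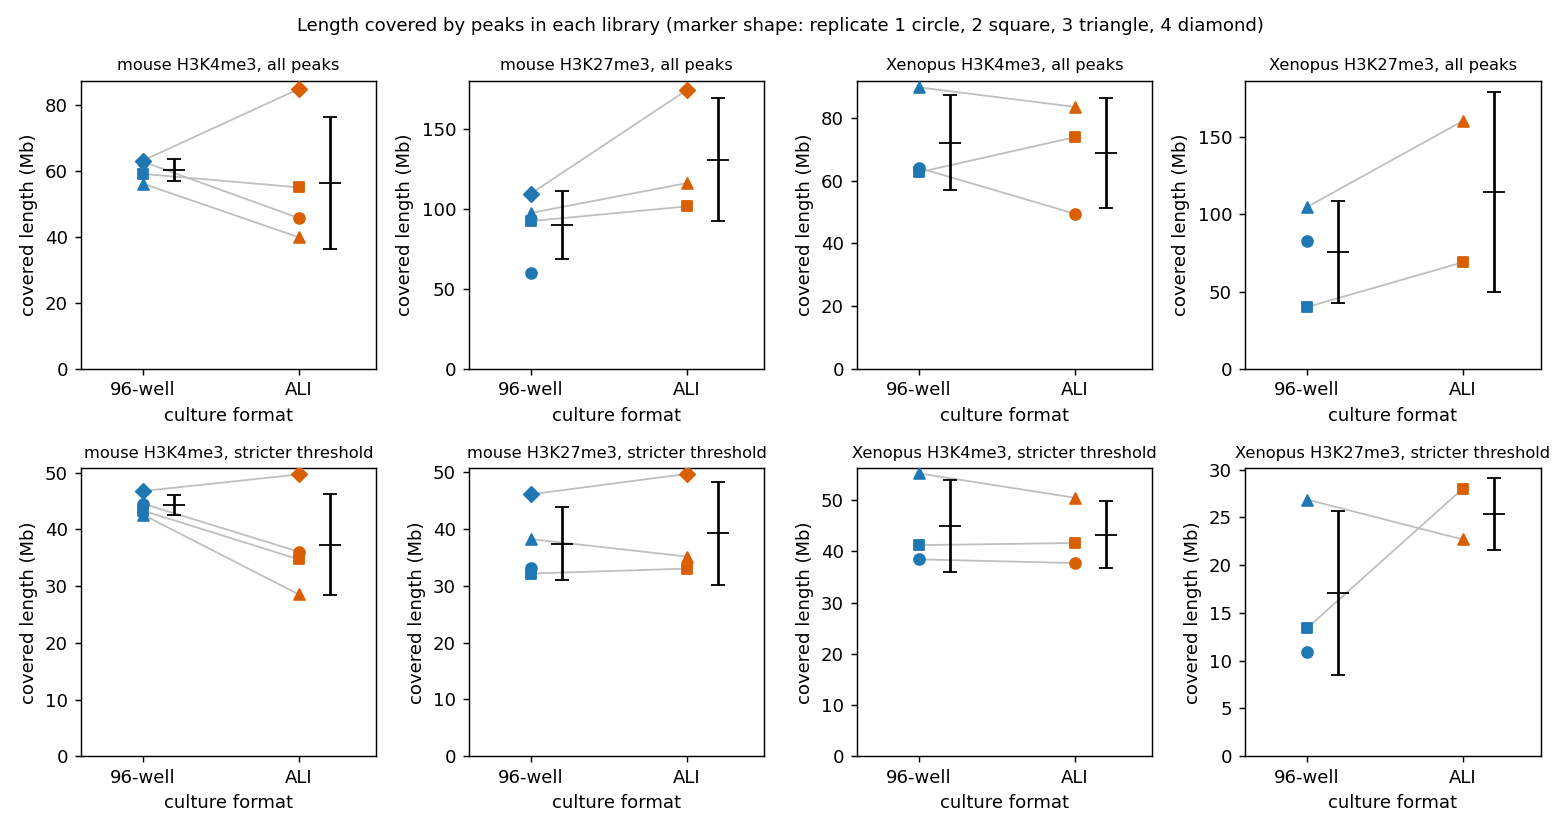
Length covered by peaks (Mb, vertical axis) in each library by culture format, with all deposited peaks in the upper row and peaks of −log10 q of 5 or more in the lower row. Symbols are libraries, grey lines join libraries of the same replicate number, and black bars are mean ± SD. For mouse H3K4me3 with all peaks, ALI replicate 4 stands at 84.8 Mb, above the 4 96-well libraries.

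No 5 kb bin of mouse H3K4me3 passed the limma test among 64099 tested, while 2866 had an unadjusted p under 0.05. The bin on chromosome 12 from 54245001 to 54250000 showed the largest difference among bins whose cultures do not overlap, 85.6% ± 11.2 (SD, n = 4) covered in 96-well and 37.0% ± 12.3 (SD, n = 4) in ALI, at an adjusted p of 0.825. The other bins with the largest differences lay on chromosome 6 from 30710001 (a difference of 44.6 points), chromosome 11 from 96190001 (43.4), chromosome 2 from 33515001 (42.9) and chromosome 15 from 102965001 (41.4). H3K27me3 peaks covered 52.1%, 2.15%, 100%, 95.9% and 98.1% on average of these bins on chromosomes 12, 6, 11, 2 and 15. In the other direction, the bins with the smallest differences lay on chromosome 8 from 21310001 (−25.1), 123205001 (−24.8) and 20155001 (−24.5), on chromosome 11 from 120700001 (−24.0) and on chromosome 5 from 15670001 (−23.3), with H3K27me3 peaks over 41.2%, 20.6%, 30.6%, 8.17% and 45.6% of them on average. All 96-well libraries exceeded all ALI libraries in 1073 bins and fell below them in 178, together 1.95% of bins, where chance gives 1.97% with ties between libraries counted (2.86% without ties). Bins of 1 kb marked in every 96-well library and no ALI library numbered 209, against 9 in the other direction. With 1 library fewer such a count can only stay or rise, and it kept its direction without each library in turn, at 298 to 1619 bins in both directions together, the highest without ALI replicate 4 (1604 against 15). With the stricter threshold, limma called 78 of 26884 bins higher in 96-well and 0 lower, and 0 with replicate number as a block, where their adjusted p ran from 0.0829 to 0.301 at a median difference of 28.9 points in both fits. With all peaks kept the median difference of these bins was 9.36 points. ALI replicates 1 to 4 then covered 29.3%, 29.1%, 18.6% and 44.5% of such a bin on average, against 39.5% to 44.2% in the 96-well libraries. Without ALI replicate 4, limma called 72 bins over all peaks and 1033 with the stricter threshold.

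Whether H3K27me3 differs between formats in mouse explants was asked next. ALI lists were longer, with 187455 ± 44482 peaks (SD, n = 3) against 112455 ± 35451 (SD, n = 4) in 96-well culture, and they covered 131 Mb ± 38.5 (SD, n = 3) against 90.0 Mb ± 21.2 (SD, n = 4). The ALI library was higher in 3 of 3 pairs on both measures. The exact permutation test gave p = 0.0571 for peak number and p = 0.114 for covered length, so neither passed. With the stricter threshold the log2 difference in covered length went from −0.54 to −0.06, and that in peak number turned to 0.22. The share of covered length on chromosome X, which takes 6.22% of the chromosome span, was 3.48%, 2.38%, 1.56% and 1.06% in 96-well replicates 1 to 4 and 6.08%, 2.61% and 1.14% in ALI replicates 2 to 4, with an exact permutation p of 0.486 between the formats. Within the 3 pairs it was lower in 96-well in 3 of 3 (−3.70, −1.05 and −0.078 points), with an exact permutation p of 0.25, the smallest that 3 pairs allow.

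**Figure D2:**
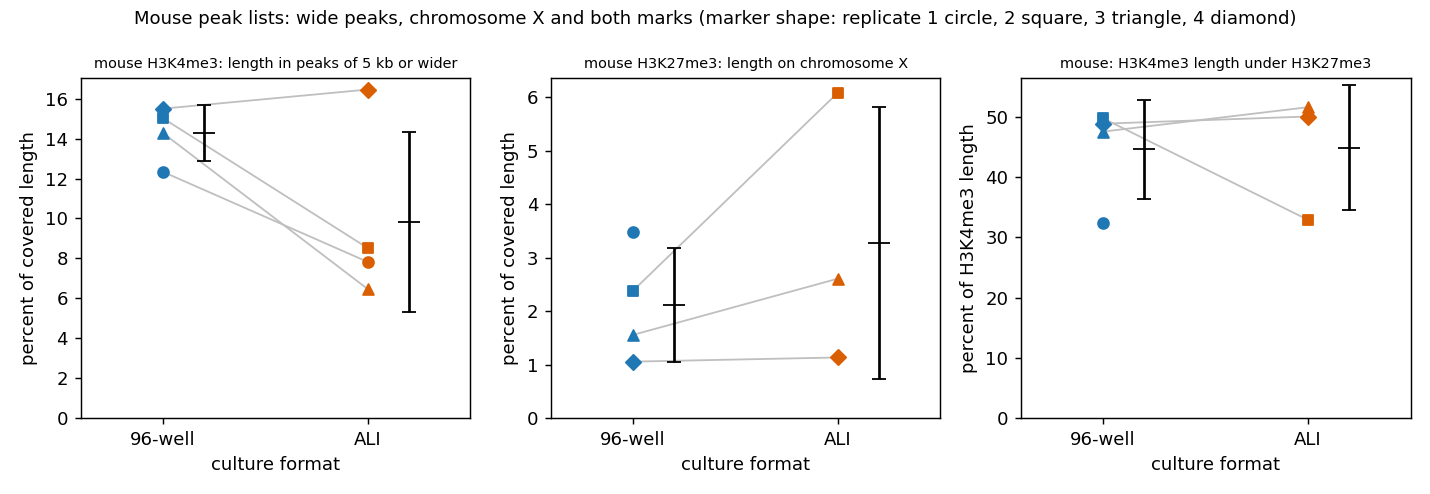
Percent of H3K4me3 length in peaks of 5 kb or wider (left), percent of H3K27me3 length on chromosome X (middle) and percent of H3K4me3 length under H3K27me3 peaks (right) in mouse libraries by culture format. Symbols are libraries, grey lines join the same replicate number, and black bars are mean ± SD. The chromosome X share runs from 1.06% to 6.08%.

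Long H3K27me3 domains were shared by the 7 mouse libraries. The longest run of marked 1 kb bins lay on chromosome 11 from 96141001 to 96246000 (105 kb), and the next on chromosome 8 from 124263001 to 124354000 (91 kb), of which 86.2% on average was also under H3K4me3. Among 141721 bins, limma called 1 higher in 96-well, on chromosome 12 from 57580001 to 57585000 (100% covered against 91.1% ± 0.336, a difference of 8.90 points, adjusted p = 0.0190), and 1 lower, on chromosome 2 from 155465001 to 155470000 (86.8% ± 1.48 against 100%, a difference of −13.2 points, adjusted p = 0.0491). Both have an SD of 0 in one culture. With replicate number as a block, which leaves fewer residual degrees of freedom, the differences were 8.90 and −13.6 points, their standard errors went from 0.513 to 0.599 and from 0.938 to 0.913, and neither passed (adjusted p = 0.564 for each). An unadjusted p under 0.05 was reached in 16849 bins. Bins in which every 96-well library fell below every ALI library numbered 12467, against 85 in the other direction, together 8.86%, where chance gives 3.82% with ties counted (5.71% without ties). Bins of 1 kb marked in every 96-well library and no ALI library numbered 21, against 1855 in the other direction, 50 against 163 with the stricter threshold and 54 against 733 with equal peak number. The direction was the same without each library in turn, at 2366 to 6709 bins together, with 34 against 6675 without ALI replicate 2 and 57 against 5854 without ALI replicate 3. Marking only in ALI takes 3 lists against 4, which favours the ALI side whatever the culture, more so without an ALI library. With a 96-well library left out the groups were equal, at 326 against 2111, 47 against 2319, 46 against 2675 and 37 against 3875 without replicates 1 to 4. Lists of the same culture overlapped more (mean Jaccard 0.454) than lists of different cultures (0.425), with a one-sided exact permutation p of 0.0286. That is the smallest possible here, and even so it could not pass adjustment over the 32 tests. Over the 3 pairs with replicate number as a block the exact permutation p was 0.25, the smallest that 3 pairs allow. The difference of 0.030 turned to −0.00078 with the stricter threshold (exact permutation p = 0.514) and fell to 0.0087 with equal peak number (exact permutation p = 0.2). Without each library in turn it ran from 0.016 to 0.050, with exact permutation p from 0.0667 to 0.2, where the smallest possible is 0.0667 without an ALI library and 0.1 without a 96-well library.

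**Figure D3:**
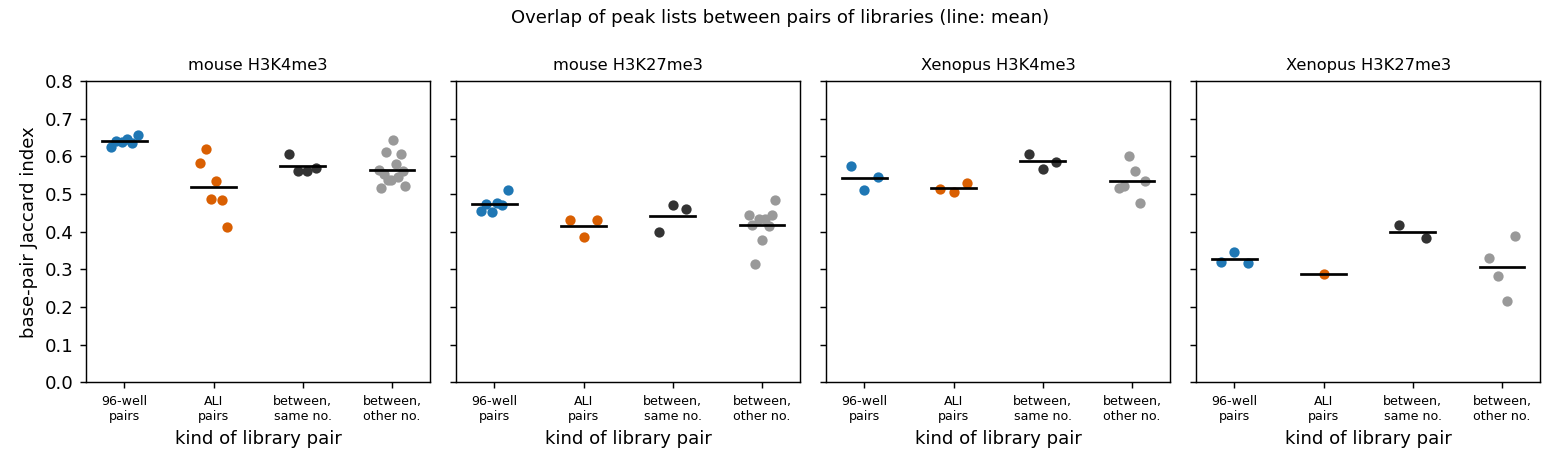
Base-pair Jaccard index (vertical axis) of each pair of libraries, by kind of pair, for each species and mark; lines are means. In Xenopus H3K4me3, pairs of different cultures with the same replicate number have a mean of 0.587, above the 0.534 of pairs with different numbers.

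In Xenopus explants H3K4me3 covered 72.2 Mb ± 15.3 (SD, n = 3) in 96-well culture and 69.0 Mb ± 17.6 (SD, n = 3) in ALI culture, with an exact permutation p of 0.9, where 0.1 is the smallest that 3 against 3 allows, and peak number gave p = 1.0. Lists with the same replicate number in different cultures overlapped more (0.587) than lists with different numbers (0.534). Lists of the same culture had a mean Jaccard index of 0.530 and lists of different cultures 0.552 (one-sided exact permutation p = 1.0). Among 105897 bins limma called 0, and 1378 had an unadjusted p under 0.05. The bin on chromosome 3L from 90155001 to 90160000 had the largest difference among bins whose cultures do not overlap, 92.4% ± 10.5 (SD, n = 3) against 52.6% ± 8.32 (SD, n = 3), and that on chromosome 7S from 93705001 to 93710000 the smallest, 15.2% ± 1.89 (SD, n = 3) against 64.1% ± 20.2 (SD, n = 3), both at an adjusted p of 1.0. The next in the first direction lay on chromosomes 3S from 11335001 (37.7 points), 8S from 88140001 (37.5), 1L from 97600001 (33.1) and 7L from 139320001 (31.3). In the other they lay on 7L from 360001 (−32.9), 5L from 168515001 (−30.0), 9_10S from 1625001 (−28.4) and 4S from 106175001 (−27.7). The non-overlapping bins were 3.65% of those tested, where chance gives 7.46% with ties counted (10% without ties) if the libraries are interchangeable. Bins of 1 kb marked only in 96-well culture numbered 265 and only in ALI culture 114. Without each library in turn they numbered 917 to 1500 together, and the direction turned without ALI replicate 1 (413 against 977) and without 96-well replicate 3 (500 against 562).

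Xenopus H3K27me3 covered 75.8 Mb ± 32.9 (SD, n = 3) in 96-well culture and 115 Mb ± 64.6 (SD, n = 2) in ALI culture, lower in 96-well in 2 of 2 pairs, with an exact permutation p of 0.6, where 0.1 is the smallest possible, and peak number also gave p = 0.6. ALI replicates 2 and 3 covered 68.9 and 160 Mb, and without ALI replicate 3 the log2 difference turned from −0.58 to 0.03. Among 178022 bins limma called 0, with 8923 at an unadjusted p under 0.05. Lists of the same culture had a mean Jaccard index of 0.317 and lists of different cultures 0.337 (one-sided exact permutation p = 0.6). Bins of 1 kb marked only in 96-well culture numbered 128 and only in ALI culture 2832. The direction was the same without each library in turn, at 4053 to 46319 together, the highest without ALI replicate 2 (300 against 46019). Marking only in ALI takes 2 lists against 3, or 1 without an ALI library, which favours the ALI side whatever the culture. With a 96-well library left out the groups were equal, at 318 against 3735, 1739 against 3192 and 231 against 7446 without replicates 1, 2 and 3. Over 5 kb bins, all 96-well libraries exceeded all ALI libraries in 919 and fell below them in 25883, together 15.1%, where chance gives 16.7% with ties counted (20% without ties). Without ALI replicate 2, which leaves 1 ALI library assumed to vary like the others, 9028 bins were called. The bins with the largest differences among those whose cultures do not overlap lay on chromosomes 3S from 127815001 (28.1 points), 8L from 20420001 (26.3), 2S from 55145001 (25.8) and 54745001 (24.2) and 5S from 54770001 (23.1). The smallest lay on 4L from 1405001 (−55.9), 9_10L from 9315001 (−48.3) and 50265001 (−44.0), 3L from 109135001 (−45.0) and 4S from 15960001 (−43.8), with adjusted p from 0.973 to 0.996 over the 10 bins.

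Xenopus laevis carries L and S subgenomes from an ancient hybridization. The L chromosomes, 54.4% of the chromosome span, held 56.2% ± 0.428 (SD, n = 3) of H3K4me3 length in 96-well and 56.3% ± 0.388 (SD, n = 3) in ALI (exact permutation p = 0.5, lower in 96-well in 3 of 3 pairs, with an exact permutation p of 0.25 over the pairs, the smallest possible), and 55.3% ± 0.225 (SD, n = 3) and 55.6% ± 0.679 (SD, n = 2) of H3K27me3 length (exact permutation p = 0.7).

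Chromatin carrying both marks is commonly read as poised. Each sample pools several limbs, so peaks of both marks need not lie in the same cells. In mouse, 44.6% ± 8.20 (SD, n = 4) of H3K4me3 length lay under H3K27me3 peaks in 96-well culture and 44.8% ± 10.4 (SD, n = 3) in ALI culture (exact permutation p = 0.943), between 7.80 and 14.7 times the share that H3K27me3 peaks take of the genome. The difference of −0.21 points turned to 3.87 without 96-well replicate 1, which stood at 32.4%, and also over the 3 pairs, to 3.16 without ALI replicate 3 and 2.39 without ALI replicate 4, and to 5.38 with the stricter threshold and 3.28 with equal peak number. It went the other way, to −6.18, without ALI replicate 2, which stood at 32.9%. In Xenopus the shares were 37.4% ± 5.85 (SD, n = 3) and 45.1% ± 5.35 (SD, n = 2), with an exact permutation p of 0.3. The level depends on weak peaks. With the stricter threshold it was 22.7% to 35.0% in mouse 96-well libraries, 14.3% to 30.9% in mouse ALI libraries and 12.6% to 32.1% in Xenopus libraries.

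The study's design sets mouse against Xenopus. The 96-well minus ALI log2 difference in covered H3K4me3 length was 0.16 in mouse and 0.08 in Xenopus, a difference of 0.08 (exact permutation p = 0.83 over 1400 regroupings). For H3K27me3 it was −0.54 in mouse and −0.58 in Xenopus, a difference of 0.05 (exact permutation p = 0.96 over 350 regroupings). With the stricter threshold it was −0.06 in mouse and −0.67 in Xenopus, a difference of 0.61 (exact permutation p = 0.329), and with replicate number as a block the difference was 0.35 (exact permutation p = 0.562), and without each library in turn it ran from −0.56 to 0.66. A species difference in the response of covered length was not detectable with these libraries.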

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

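The tests of weak peaks and of chromosome X, and the split counts over all peaks, were chosen after the results were seen. In 3 of 22 checks, a library lay far from the other 3 of its group. The checks were 7 measures in each of 3 groups of 4 libraries and 1 further measure of the mouse 96-well samples. Chance gives such a library in about 5% of checks, and the measures of a group are not independent of each other. In mouse H3K27me3, 96-well replicate 1 had 59789 peaks where the other 96-well libraries had 123355 to 135000. In mouse H3K4me3, ALI replicate 4 had 155 peaks of 10 kb or wider where the other ALI libraries had 18 to 34. In mouse 96-well culture, 32.4% of the H3K4me3 length of replicate 1 lay under H3K27me3 peaks, against 47.5% to 49.7% in the others.

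Signal also lay outside the nuclear chromosomes. The spike-in sequence was called as a peak in 26 of 26 lists, at a fold enrichment of 17.1 to 95.4, above every nuclear peak in 10 lists. The mitochondrial genome was called in 26 of 26 lists, at a fold of 13.8 to 81.7.

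Mouse H3K27me3 lists of ALI culture covered more of the genome than those of 96-well culture, by a log2 difference of −0.54 (96-well minus ALI). If weak peaks near the calling threshold carried this, the difference would shrink to less than 50% of its size among strong peaks, and at −log10 q of 5 or more it was −0.063. That fits an origin in weak peaks, which may reflect depth or background of the libraries, and depth is unknown here. A response of H3K27me3 to the culture format stays open as untested, since a weak mark spread over many regions would also appear as weak peaks. The exact permutation p of the difference over all peaks was 0.114.

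The chromosome X share of mouse H3K27me3 differed 5.75-fold between its highest and lowest library. Among strong peaks the ratio fell to 1.85, so weak peaks may carry much of the spread. The share also fell in order of replicate number in both cultures. It was 3.48%, 2.38%, 1.56% and 1.06% in 96-well replicates 1 to 4 and 6.08%, 2.61% and 1.14% in ALI replicates 2 to 4. Among strong peaks it fell in the same order, at 2.01%, 1.31%, 1.29% and 1.12% in 96-well and 1.57%, 1.40% and 1.09% in ALI. Replicate number goes with the date-like stamp, and a difference between stamps was not tested. ALI replicate 2, with the highest share over all peaks, has no H3 sample of its own in the series. An effect of the H3 control was not tested. The sex of the pooled limbs is a further candidate explanation. It predicts a negative relation with the chromosome Y share of H3K4me3 in the sample of the same culture and number, and Spearman's rho was −0.39 (exact permutation p = 0.396, n = 7) and Pearson's r −0.51 (exact permutation p = 0.227, n = 7; adjusted p 0.498 for each over 4 relations), with r at −0.61 without the 2 samples farthest from the median. Between the cultures of replicate numbers 2, 3 and 4, the X and Y shares moved in opposite directions in 1 pair and in the same direction in 2, and with 7 samples and 3 pairs sex cannot be told apart from chance.

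For counts across bins, other splits of the same libraries give the level that chance can reach. Any split reaches a count of 0, so the 35 of 35 splits of mouse H3K4me3 (highest other 1) and the 10 of 10 splits of Xenopus H3K4me3 (highest other 0) with at least the real 0 changed 5 kb bins say nothing about chance. For bins of 1 kb marked in one group only, 7 of 35 splits of mouse H3K4me3 gave as many as the real 218 (highest other 723). In mouse H3K27me3, 5 of 35 splits gave as many changed bins as the real 2 (highest other 31), and 4 of 35 as many exclusive bins as the real 1876 (highest other 2449). Chance cannot be excluded for these 3 counts. The 10 splits of Xenopus H3K4me3 are too few for a share under 0.05, and 7 gave as many exclusive bins as the real 379 (highest other 2099). The 10 splits of Xenopus H3K27me3 are too few likewise, with a real count of 2960 and a highest other of 13902.

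Some splits gave several times the real count. The splits with 723, 31, 2099 and 13902 bins each left at least 1 pair of the same replicate number together. Most splits do so, since only 8 of 35 in mouse and 4 of 10 in Xenopus part every pair. Each of these splits also set the libraries with the most covered length against those with the least. In the split with 723 bins, 59.1 to 84.8 Mb stood against 39.9 to 56.1 Mb. Replicate pairing and list length were not told apart. Among the splits that part every pair, the highest other count of exclusive bins was 306 in mouse H3K4me3, above the real 218, and it was below the real count elsewhere, at 1044 in mouse H3K27me3 (8 splits), 362 in Xenopus H3K4me3 (4 splits) and 1495 in Xenopus H3K27me3 (4 splits). For changed bins of mouse H3K27me3 it was 0, against the real 2.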

How the results depend on the processing

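Over 294 alternative values, 189 kept their direction and side of the threshold, or a count within 1.5 times, 35 changed sign, 9 lost and 4 gained the threshold, and 57 counts moved further. The cause of these changes was not tested. In Xenopus the exact permutation tests of library values and overlap allow no p under 0.1. Those values could change sign but not cross the threshold, so keeping their side of it was fixed in advance. Leaving out a library raises the smallest possible p of the exact permutation test in mouse H3K27me3, but in mouse H3K4me3 it stays at 0.0286. Depth is unknown and limits every count. With the stricter threshold the log2 difference in peak number turned to 0.12 in mouse H3K4me3 (from −0.09) and 0.22 in mouse H3K27me3 (from −0.78), the overlap difference of mouse H3K27me3 to −0.00078, the L share to 0.0017 points for H3K4me3 and 0.10 for H3K27me3, and the mouse share under both marks to 5.38 points (3.28 with equal peak number, 3.87 with replicate number as a block, from −0.21, all added after seeing the data). The overlap difference of mouse H3K27me3 fell to 0.016 with replicate number as a block, where 3 pairs allow no p under 0.25, and to 0.0087 with equal peak number, where it did not pass.

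Exclusive bins numbered 27 with 5 kb bins in mouse H3K4me3. They numbered 213, 787, 290 and 6959 in mouse H3K27me3 with the stricter threshold, equal peak number, 5 kb bins and any base covered, 739, 1616, 177 and 16843 in Xenopus H3K27me3 likewise, and 225, 29 and 1009 in Xenopus H3K4me3 with the stricter threshold, 5 kb bins and any base covered. Changed 5 kb bins of mouse H3K4me3 went from 0 to 78 with the stricter threshold and 1 with 2 kb bins. In mouse H3K27me3 they went from 2 (1 higher, 1 lower) to 18 (4 higher, 14 lower) with the stricter threshold, 1 with equal peak number, 12 with 2 kb bins, and 0 each with replicate number as a block, quantile normalization, covered length as a covariate and 10 kb bins. In Xenopus H3K27me3 4 bins were called with quantile normalization. The 78 stricter-threshold bins became 0 with replicate number as a block, at the same differences with fewer residual degrees of freedom. With covered length as a covariate 39 of the 78 stayed past the threshold, among 40 bins called. Apart from these bins and those of mouse H3K27me3, the block changed no count of changed bins. The 2 kb and 10 kb bins, the alternatives of the stricter-threshold bins, and leaving out libraries for the share in wide peaks, were chosen after seeing the data.

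Leaving out 1 library at a time gave these ranges. Peak number ran from −0.28 to 0.10 in mouse H3K4me3, −0.96 to −0.50 in mouse H3K27me3, −0.36 to 0.36 in Xenopus H3K4me3 and −1.21 to −0.17 in Xenopus H3K27me3. Covered length ran from 0.011 to 0.37 in mouse H3K4me3 (the highest without ALI replicate 4), −0.70 to −0.31 in mouse H3K27me3, −0.14 to 0.24 in Xenopus H3K4me3 and −1.19 to 0.027 in Xenopus H3K27me3. The share of mouse H3K4me3 length in peaks of 5 kb or wider ran from 3.36 to 6.68 points (only the highest, without ALI replicate 4, passed, before any adjustment). The overlap difference ran from −0.0093 to 0.047 in mouse H3K4me3 (past the threshold without ALI replicates 1 and 4), 0.016 to 0.050 in mouse H3K27me3 (not past the threshold in any, where the fewer libraries allow none) and −0.052 to 0.032 in Xenopus H3K27me3. Exclusive bins ran from 298 to 1619 in mouse H3K4me3, 2366 to 6709 in mouse H3K27me3, 917 to 1500 in Xenopus H3K4me3 and 4053 to 46319 in Xenopus H3K27me3. Changed bins ran from 0 to 72 in mouse H3K4me3 (72 without ALI replicate 4), 0 to 13 in mouse H3K27me3 (13 without 96-well replicate 4), 0 to 9028 in Xenopus H3K27me3 and 51 to 1033 among the stricter-threshold bins (1033 without ALI replicate 4). The L share ran from −0.41 to 0.060 points for H3K4me3 and −0.77 to 0.19 for H3K27me3, the share under both marks from −6.18 to 3.87 in mouse and −11.4 to −3.84 in Xenopus, and the species difference from −0.078 to 0.30 for H3K4me3 and −0.56 to 0.66 for H3K27me3.

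Gene lists, promoters with both marks and other promoter windows were not run, since no annotation of the build was used. Bins without a peak in any library have no spread, so the fit without the filter kept bins touched in at least 1 library.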

Other observations

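The stricter threshold was planned, the 78 bins described here were followed up after their count was seen, and the tests of them were written before their results. In Xenopus, 4 of the 5 longest runs of marked 1 kb bins were the same for both marks. On chromosome 7L, the runs from 92859001 to 92943000 (84 kb), from 93130001 to 93213000 (83 kb) and from 93452001 to 93511000 (59 kb), and on chromosome 2S the run from 85826001 to 85880000 (54 kb), were marked in every H3K4me3 and every H3K27me3 library, with 98.8% to 99.7% of their length under the other mark on average. In mouse, the run on chromosome 9 from 3000001 to 3038000 (38 kb) was under H3K4me3 in every library and 100% under H3K27me3. Whether such runs carry both marks or gather signal whatever the antibody was not tested. Long H3K27me3 runs nearly free of H3K4me3 lay on chromosome 7 from 79142001 to 79213000 (4.0% under H3K4me3) and chromosome 9 from 91231001 to 91290000 (4.7%).

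Among strong peaks, 78 mouse H3K4me3 bins in 74 separate runs were higher in 96-well culture. The bins with the largest differences were named after their values were seen. They lay on chromosome 16 from 17620001 to 17625000 (100% against 8.07% ± 9.48 covered, n = 4 each) and on chromosome 8 from 124290001 to 124295000 (96.6% ± 3.89 against 10.2% ± 11.8) and 93090001 to 93095000 (76.4% ± 13.9 against 0%). The others lay on chromosome 7 from 30750001 to 30755000 (95.5% ± 5.20 against 29.8% ± 20.1) and chromosome 5 from 125235001 to 125240000 (58.9% ± 4.39 against 0%). The bin from 124290001 lies in the 91 kb run of chromosome 8 that every mouse H3K27me3 library shared. With all peaks kept, H3K4me3 covered 60.7% to 96.1% of that run in each library, so the bin's difference among strong peaks need not be a local gain.

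A library-wide difference in peak strength stays open as a cause. Quantile normalization left the median difference of the 78 bins at 24.2 points (SD 16.6 across bins) from 28.9 (SD 16.6). After it, 56 of them stayed past the threshold. With covered length as a covariate the median difference was 28.0 points (SD 15.8) and 39 stayed. Neither correction can decide the question, since peaks under the stricter threshold had been removed before it and could not be restored. The 78 bins had also been selected for their difference. Whole peaks crossing the stricter threshold may account for most of the difference: with all peaks kept, its median fell to 9.36 points (SD 9.29), and ALI replicate 4 covered 44.5% of these bins against 39.5% to 44.2% in the 96-well libraries. ALI replicates 1, 2 and 3 stayed lower, at 29.3%, 29.1% and 18.6%, and 71 of the 78 bins stayed higher in 96-well on average. The count depends on single libraries, at 1033 without ALI replicate 4 (all 78 among them), 135 and 153 without 96-well replicates 2 and 3, and 51 without ALI replicate 3. With replicate number as a block 0 bins were called, because the residual degrees of freedom fell from 6 to 3 while the median difference stayed at 28.9 points with a median standard error of 2.80 (from 2.81), and the adjusted p of the 78 ran from 0.0829 to 0.301. Chance cannot be excluded, since 3 of 35 splits called as many bins (highest other 115, in a split that left pairs 2 and 4 together), although the other splits that part every pair called at most 2, and a response of H3K4me3 to the culture format stays open.

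A hypothesis is that these bins lie in chromatin that also carries H3K27me3. Strong H3K27me3 peaks covered 50.5% of the 78 bins on average, at 46.6% to 57.8% in each of the 7 H3K27me3 libraries. In 10000 draws of bins with like mean H3K4me3 cover it was 16.7% (95% of draws between 10.8% and 23.6%). The draws were matched on mean cover at the stricter threshold only, not on peak strength. They cannot separate an effect of culture from H3K4me3 peak strength that differs in chromatin with H3K27me3. If bins that vary between libraries lay in such chromatin whatever the split, the split with 115 bins would show it too, and there the value was 21.3%, under its upper bound of 22.4%. A split with 83 bins also stayed under its upper bound (15.1% against 24.2%). Other splits, with 36 and 51 bins, did exceed their bounds (33.3% against 27.5% and 27.03% against 24.7%), so part of the excess may belong to variable bins in general.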
